A study of Mus musculus with 384 samples.

How the data were processed

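Single CLPs from mouse bone marrow were sorted into 4 plates, each with 90 wells of 1 cell, 4 no-RT wells, 1 well of 10 cells and 1 well of 20 cells. Per the labels' protocols, cells were sorted into lysis buffer and frozen, and reverse transcription and pre-amplification were run in the well with all 96 TaqMan assays. Per the labels' protocols, no-RT wells received Taq enzyme without reverse transcriptase, and the products were read on a Fluidigm dynamic array on a BioMark HD instrument. The deposited values are Ct, a cycle number on a log2 scale with the sign turned, as the authors deposited them without normalization. The software and threshold behind the Ct are not given in the sources used here. The 36864 values ran from 5.71 to 40; 58.2% were at 40, taken as no product, and 22 lay between 28 and 40. Columns were tied to samples by their titles, and 0 columns were left unmapped. Pre-amplification multiplies every product and a late Ct rests on few molecules, so a missing product means that a transcript was not detected at this sensitivity, which is not known per assay.

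Of the 96 assay names, 47 matched a current symbol and 34 a synonym of 1 gene in a RefSeq gene table of the assembly GRCm38.p6, used for names only; 15 matched none and keep the name of the file (for example FOX01 and CD284). Positions of the assays in the genome were not analysed here.

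A product was a Ct below 28, and the level was 28 minus Ct. A single-cell well was kept if it had a product for more than 50% of the panel's reference genes and at least 50% of its plate's median number of assays; 13 of 360 were left out. Of these, 10 were identical columns with no product, and no other columns were identical. Detection is given as the share of kept cells per plate, with mean and SD over 4 plates; limits for 0 cells use 3 counts, and intervals are exact at 95%. Cells were never used as replicates.

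Tests used limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05. Detection in cells and no-RT wells was compared on the arcsine of the square root of the share per plate. Levels of 20-cell and 10-cell wells were compared for assays with a product in at least 3 of 4 wells of each group, and 10-cell wells were set against 10 times the mean of 2 to the power of 28 minus Ct over the single cells of the plate. Median levels per well were compared by an exact two-sided permutation test, inverted for the 95% interval. Co-detection of 2 genes was the log2 odds ratio within a plate with 0.5 added to each cell of the table, tested against 0 across plates by an intercept-only limma model. It took genes with a product in 5% to 95% of cells and in fewer than 4 of 16 no-RT wells. Gene lists (reference, sort markers, B lymphoid, lymphoid priming, T lymphoid, NK and innate lymphoid, myeloid, dendritic, erythroid and megakaryocyte, stem and multipotent, proliferation) were tested by their mean log2 odds ratio per plate. Groups, lists, tests and all alternatives except those named as added were chosen before the data were examined.

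Genes are named by a rule fixed with them: the sort markers, the 2 most and 2 least often detected members of each list among those in at least 1% of cells, members found in no cell, the 10 pairs with the largest positive and the 10 with the largest negative log2 odds ratio past the threshold with the same sign on all plates, and up to 5 assays per direction in other tests. Further genes (among them Csf3r, Cd68 and H2-K1) were chosen after their values were seen. Some genes that the rule takes, and a test that needs one of them, are not reported here.

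The plate is a batch shared by the groups and so pairs them by the labels; the fits were made without the plate as a block, and the block was an alternative. Deviations of wells of the same plate from their group means correlated between -0.19 and 0.05 for no-RT wells and cells, between -0.66 and 0.01 for 10-cell and 20-cell wells, and between -0.57 and 0.75 for 10-cell wells and cells, across assays.

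Each test was tested on simulated data over 20 runs. For detection above no-RT with 88 assays, 100% of 20 changed assays were recovered with a mean of 11.8 false calls. Of these false calls, 6.55 were assays in under 20% of cells and 4.25 in over 80%. An exact upper limit, added after this, recovered 90.8% with 0.15 false calls. Neither recovery was given separately for assays in under 20% of cells, which made up 25 of the 74 calls in the data. The lowest exact limit, 20.6%, lies above such shares, so these assays cannot pass it. The 90.8% therefore does not hold for them. For 20-cell against 10-cell wells with 59 assays, 62% of shifts of 1 cycle and 99.5% of shifts of 2 cycles were recovered at the spread of the 20-cell wells, and for 10-cell wells against single cells with 61 assays 59% and 100%. These simulated wells had independent noise per assay. The measured 10-cell wells varied more, with an SD of the median level of 7.23 (1.17 without that of plate P0) against 0.25 in the 20-cell wells. The recovery therefore does not hold for the measured pooled wells. For co-detection with 1176 pairs, 12.8% of seeded pairs with a log2 odds ratio of 2 and 77.5% with 3 were recovered, and 0 pairs were called when genes were independent or when cells differed in yield alone. With yield alone, up to 3 of 36 list pairs were called, with list means up to 0.96.

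The alternatives were Ct limits of 25 and 40, each plate left out, the plate as a block, no or stricter quality control, untransformed shares, all assays at the limit, centring on reference genes, geometric means, odds ratios within cells split by the number of other genes or by reference gene Ct, centring per plate, genes in 10% to 90% of cells, no-RT assays kept, and a pseudocount of 1. Python 3.11.15 and matplotlib 3.10.9 drew the plots.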

Results

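Common lymphoid progenitors (CLPs) are bone marrow cells that can still give rise to B, T, natural killer and dendritic cells. Single CLPs of wild-type C57/Bl6 mice were sorted as lineage-negative, B220-negative cells with Flt3 and Il7r at the surface and low Kit and Sca1. The cDNA of each cell was pre-amplified and read by quantitative PCR with 96 TaqMan assays. The series holds 384 wells on 4 plates, P0 to P3: 360 wells with 1 cell, 16 wells without reverse transcription (no-RT), 4 wells with 10 cells and 4 wells with 20 cells. The labels place its subject, heterogeneity in early lymphoid compartments, within this gate, so the comparisons ask which lineage genes are transcribed in its cells and which of them are found in the same cells. A value is the cycle at which a product crossed the detection threshold (Ct), so a lower Ct means more cDNA, and the file's value of 40 stands for no product.

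Of the 360 single-cell wells, 86 passed quality control on plate P0 and 87 on each other plate. The passing cells had a product for 22 to 54 of the 96 assays (median 43). The no-RT wells had a median of 6.5 assays with a product. Of the 13 wells left out, 10 had no product at all. The plate was taken as the replicate (n = 4). Since the labels do not say that plates came from separate animals, p-values rest only on the spread between plates, which may be technical. Limma also draws the spread of each assay, pair or list pair toward that of the others in its test.

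Some lymphoid and multipotent genes were detected in nearly all cells of the gate, and others, B lineage genes among them, in part of them. Kit, the only sort marker with a matched assay, was detected in 97.4% ± 1.1 of cells (mean ± SD over plates, n = 4, as for all shares here). Ikzf1 and Notch1, transcription regulators of early lymphoid cells, were detected in 99.7% ± 0.57 and 98.3% ± 0.66, and Spi1, a myeloid and B cell transcription factor, in 98.8% ± 1.6. Ebf1 and Ly6d, early B lineage genes, were detected in 73.8% ± 6.0 and 70.3% ± 4.6 of cells. Pax5, the B lineage commitment factor, was detected in 25.9% ± 2.0. Of the 96 assays, 18 gave a product in more than 95% of cells, 55 in 5% to 95%, 15 in fewer than 5%, and 8 in none.

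**Figure D1:**
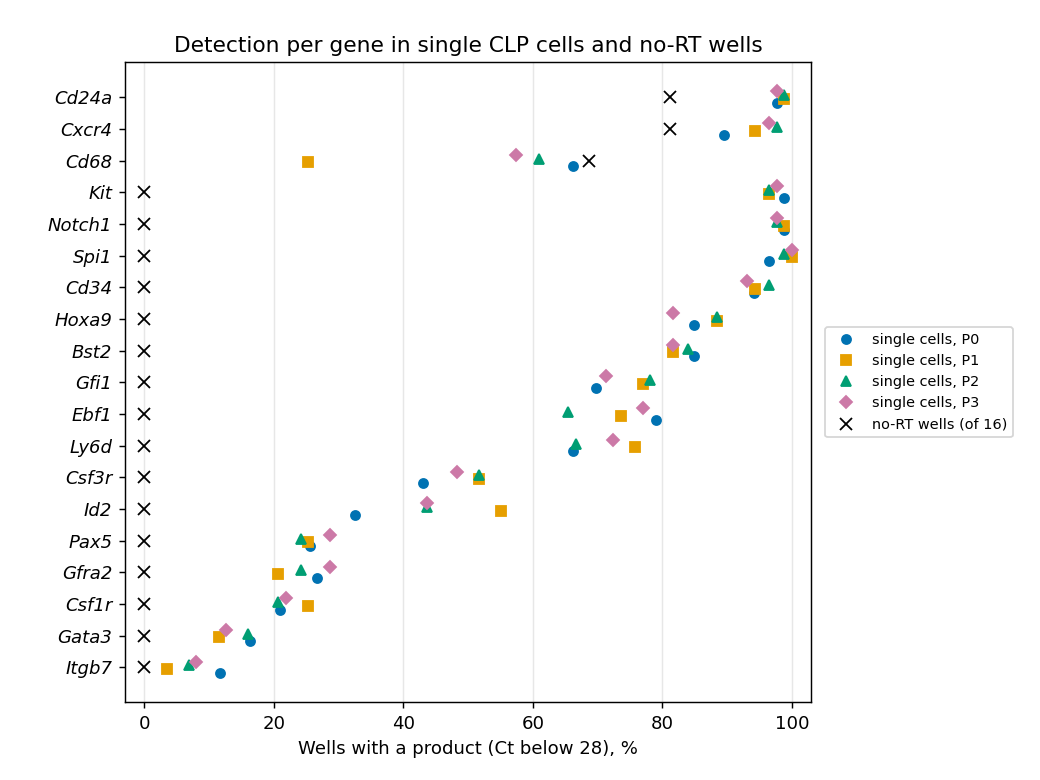
Percent of wells with a product (Ct below 28) for 19 genes: coloured points give the single cells of each plate, P0 to P3, and crosses the 16 no-RT wells. Kit lies at 97.4% of cells on average, Ebf1 at 73.8% and Pax5 at 25.9%, all with no product in no-RT wells, while Cd24a had a product in 13 of the 16 no-RT wells.

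Nearly all cells had a product for at least 1 gene of most lists, chiefly through members found in almost every cell, such as Bcl11a, Notch1, Itga4, Spi1 and Tfrc. Of the B lymphoid list, 8 members were measured: Bcl11a was detected in 98.3% ± 1.5 of cells, Spib in 2.02% ± 1.1 and Lef1 in 1.74% ± 2.2. The Lef1 share was 4.65% on plate P0, 2.30% on P1 and 0% on P2 and P3, or 0.766% without P0, and Lef1 was not called above no-RT wells. In all, 98.6% ± 1.1 of cells had a product for at least 1 of the 7 members that no-RT wells did not also yield. Cd24a, the B lymphoid member at 98.3% ± 0.67, is read with its no-RT background, a product in 13 of 16 wells. Of the 9 lymphoid priming genes, 6 were in more than 95% of cells; Ccr7, a chemokine receptor, was in 69.8% ± 4.7. Among 7 T lymphoid genes, Gata3, a T and innate lymphoid transcription factor, was detected in 14.1% ± 2.4, Cd4 in 10.9% ± 3.5 and Cd5 in 9.78% ± 6.2. Cd3e and Cd2 were detected in 0 of the passing cells, which allows a share of cells with a product of up to 0.865%. Of 8 NK and innate lymphoid genes, Itga4 was in 99.1% ± 1.1, Cd244a in 90.8% ± 2.5, Klrb1c, a natural killer cell receptor, in 13.3% ± 4.8, Itgb7 in 7.50% ± 3.4, and Tbx21 in 0 of the passing cells. These limits cover counting error only. Cd3e, Cd2 and Tbx21 had no product in any pooled well either, nor had H2-D1, a class I histocompatibility gene, so that an assay that does not work is not excluded and the limits say nothing of cells with the transcript.

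Of 7 myeloid genes, Gfi1 was detected in 74.1% ± 4.2 of cells, Csf3r, the G-CSF receptor, in 48.7% ± 4.1, Il6ra in 17.3% ± 2.5 and Klf4 in 14.1% ± 6.1. In this list, 99.4% ± 0.67 of cells had at least 1 such gene. Of 6 dendritic genes, Bst2, an interferon-inducible surface protein, was in 83.0% ± 1.7 and Csf1r, the M-CSF receptor, in 22.2% ± 2.1; 98.6% ± 1.4 of cells had at least 1. Of 4 stem and multipotent genes, Cd34 was in 94.5% ± 1.5, Hoxa9 in 85.9% ± 3.3 and Fli1 in 49.3% ± 6.1; 98.9% ± 0.94 of cells had at least 1. Of 5 erythroid and megakaryocyte genes, the transferrin receptor Tfrc was in 99.1% ± 0.58, Cd9 in 29.1% ± 3.8 and Il3ra in 18.7% ± 3.9. The proliferation list was represented by Gfi1 alone, and the reference genes Atp5a1, Tfrc and Hprt were in at least 98.8% of cells. At least 1 member of the lymphoid priming, NK and innate lymphoid, erythroid and megakaryocyte and reference lists was found in 100% of cells, and at least 1 T lymphoid gene in 99.1% ± 1.1.

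The no-RT wells show which of these products need reverse transcription. Atp5a1, H2-K1 and Itga4 had a product in at least 99.1% of cells and in 0 of 16 no-RT wells, and the same held for Kit, Ebf1, Ly6d, Pax5 and Csf3r at their own shares. Of 88 assays with a product in either group, 74 were detected more often in cells (limma, adjusted p under 0.05) and 0 less often (0 at an unadjusted p under 0.05). Among the 14 assays not called were CDw199, with a product in 14 of 16 no-RT wells, Cxcr4 (13), Cd24a (13), Nfil3 (12), Fut4 (12), Cd68 (11) and Cebpa (7). With only 16 no-RT wells the test made false calls on simulated data, chiefly for assays in few or nearly all cells (a mean of 11.8 among 88 assays). A stricter criterion added after seeing this, a share above the exact 95% upper limit of the no-RT wells on every plate, was met by 47 assays, 46 of them among the 74. It was not met by Bst1, Klrb1c, Gata3 or Itgb7, whose shares lie near or under the 20.6% that 0 of 16 wells allows.

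Wells with 20 cells yielded products for 71 to 78 assays and 3 of the wells with 10 cells for 68 to 71, where the detection shares of the same plate's single cells predicted 69.6 to 76.9 (not tested). The 10-cell well of plate P0 had 29, against 71.4 predicted. Median levels (28 minus Ct, so that 1 unit is 1 cycle or a doubling) over the 28 assays found in all 8 wells were 13.20 ± 7.23 in the 10-cell wells and 17.93 ± 0.25 in the 20-cell wells (SD, n = 4 each). The difference of 4.74 cycles had an exact two-sided permutation p of 0.0857 (n = 4 and 4, smallest possible 0.0286), and its 95% interval, -0.43 to 15.7, holds both 0 and the 1 cycle that 20 cells in place of 10 would give. With levels centred on the reference genes the difference turned to -0.23 cycles (exact permutation p = 0.543). Centring takes out a shift shared by all assays of a well, so this value cannot show an effect of cell number. By limma, 0 of 59 assays differed (4 higher in 20-cell wells at an unadjusted p under 0.05). Without the 10-cell well of plate P0, a choice made after seeing the data, the difference over the same 28 assays was 1.15 cycles (exact permutation p = 0.0857 with n = 3 and 4). Over the 56 assays that then entered it was 1.33 cycles (interval -0.13 to 2.94, exact permutation p = 0.0571 with n = 3 and 4) and 1 of 59 assays was called, Zfp521, a zinc finger transcription factor of progenitor cells, 2.93 higher in the 20-cell wells (adjusted p = 0.0249, limma).

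**Figure D2:**
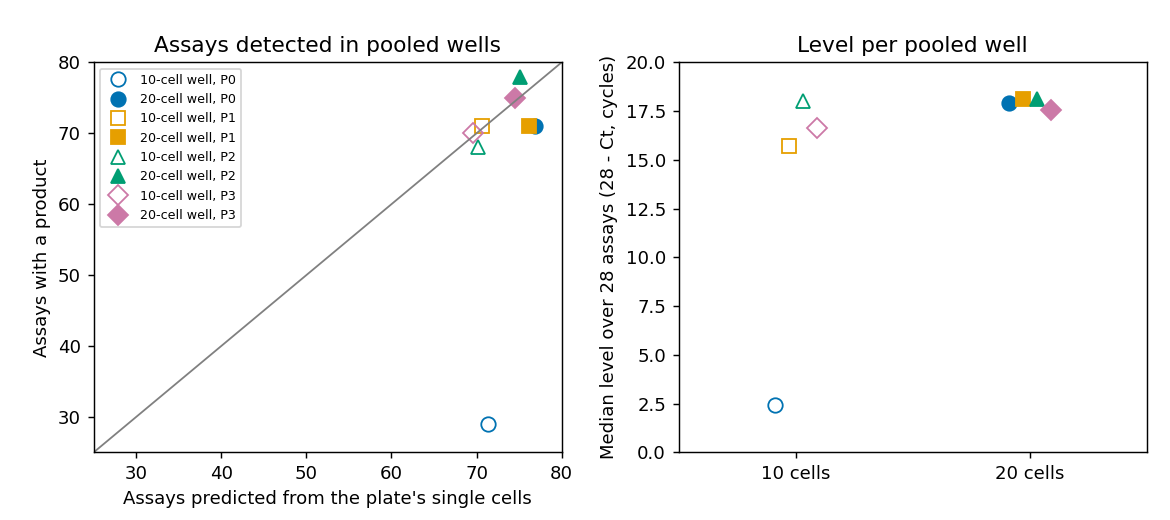
Left, assays with a product in each pooled well against the number predicted from the single cells of its plate, with the line of equality; right, the median level of each pooled well over 28 assays in cycles (28 - Ct). Open symbols are 10-cell wells and filled symbols 20-cell wells; the P0 10-cell well lies apart with 29 assays.

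The average of the single cells was set against the 10-cell well of the same plate. Over 29 assays found in all 10-cell wells, the 10-cell wells had a median level of 13.13 ± 7.11 and 10 times the mean single cell a level of 17.04 ± 0.30 (SD, n = 4 each), a difference of -3.92 cycles (95% interval -14.8 to 1.31, exact permutation p = 0.314, n = 4 and 4). By limma, 0 of 61 assays differed (1 higher and 1 lower in the 10-cell wells at an unadjusted p under 0.05). Without the well of plate P0 the difference over the same 29 assays was -0.40 cycles (exact permutation p = 0.6, n = 4 and 3). Over the 61 assays that then entered it was -0.73 cycles (interval -2.27 to 0.77, exact permutation p = 0.343, n = 4 and 3) and 0 assays were called (1 higher and 3 lower at an unadjusted p under 0.05).

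Within the gate, B lineage genes were found together in the same cells. Pax5 was detected with Ebf1 in 89 cells and without it in 1, where independent detection would give 66.6 cells with both; the log2 odds ratio within plates was 4.21 ± 0.98 (SD, n = 4 plates, limma adjusted p = 0.00116). Gfra2, a receptor of the GDNF family, went with Pax5 as strongly, at 4.12 ± 0.36 (adjusted p = 6.97e-04), and Ly6d with Pax5 at 3.85 ± 1.24 and with Ebf1 at 3.71 ± 1.06 (adjusted p = 0.00243 each). Cells with a product for Ebf1, Ly6d and Pax5 together numbered 87 against 46.9 under independence. Cells with none of them numbered 62 against 20.2. Ebf1 and Ly6d without Pax5 were found in 37.2% ± 2.9 of cells, and the number of these cells was slightly under the 133.2 that independence would give. Pax5 without Ebf1 and Ly6d was found in 1 cell (6.96 under independence), Pax5 and Ebf1 without Ly6d in 2 (19.7) and Pax5 and Ly6d without Ebf1 in 0 (16.5).

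Other genes were detected with or apart from this group. Bst1, a surface enzyme of lymphoid progenitors, was found with Ly6d (3.29 ± 1.03), Gfra2 (3.12 ± 0.62) and Pax5 (3.00 ± 1.40), the FOX01 assay with Pax5 (3.40 ± 0.80), and Gfra2 also with Ly6d (2.81 ± 1.75) and Ebf1 (2.80 ± 1.00). Among the negative pairs, Csf3r was found apart from Gfra2 (-3.02 ± 1.24), Ebf1 (-3.01 ± 0.78), Pax5 (-2.88 ± 0.97) and Ly6d (-2.57 ± 0.67), and Cd34 apart from Gfra2 (-4.002 ± 1.61), Pax5 (-2.76 ± 2.02) and Cd38 (-2.32 ± 0.59). The gut-homing integrin gene Itgb7 was found apart from Ebf1 (-2.42 ± 0.56) and Pax5 (-2.36 ± 0.78), with 0 cells holding both Itgb7 and Pax5 against 6.78 under independence. With no such cell, the size of this value is set by the pseudocount of 0.5, a pseudocount of 1 gave -1.49, and cells split by number of genes or by reference Ct gave -1.48, with the call kept. Hoxa9 was found apart from Ly86, a receptor accessory protein (-2.28 ± 0.73). All values are log2 odds ratios with SD over 4 plates, and these 20 pairs had an adjusted p of at most 0.038 (limma).

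**Figure D3:**
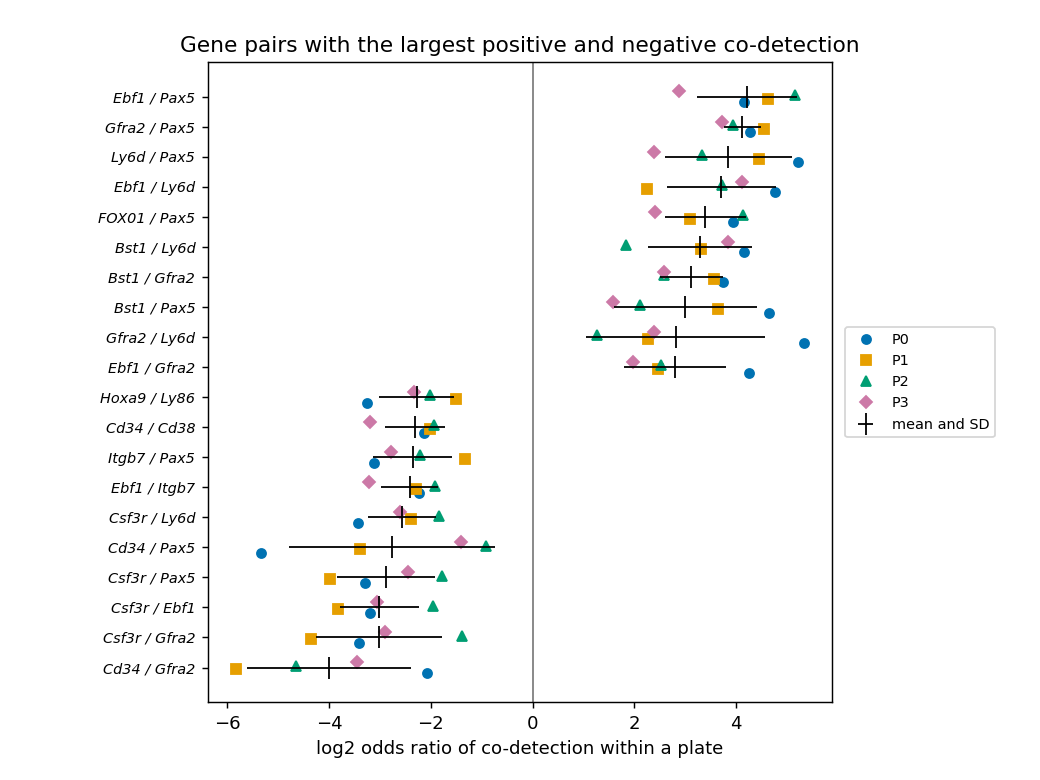
Log2 odds ratio of co-detection within each plate (coloured points, P0 to P3) for the 10 gene pairs with the largest positive and the 10 with the largest negative mean; black marks give the mean and SD over 4 plates. All plates lie on the same side of 0 for each pair, from Ebf1 with Pax5 at 4.21 to Cd34 with Gfra2 at -4.002.

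In all, 49 genes made 1176 pairs, of which 35 were positive and 19 negative (limma, adjusted p under 0.05), each with the same sign on all 4 plates. Pax5 took part in 12 of them, and Ebf1, Ly6d, Gfra2 and Cd34 in 9 each. On plate P2, where CD284 had no product, the signs of its positive pairs with Tnfrsf4 and Itgax come from the pseudocount alone. Centring each plate on its mean pair gave 23 positive and 20 negative pairs, 53.5% positive against 64.8% without centring. With 3 plates in place of 4, 25 pairs were called without P0, 11 without P1, 43 without P2 and 15 without P3. Of the 20 pairs given above, 16, 10, 20 and 12 stayed called. Gfra2 with Ly6d, Cd34 with Pax5 and Hoxa9 with Ly86 lost their call without P0, P1 or P3. Csf3r with Gfra2 and with Ly6d, Ebf1 with Itgb7 and Cd34 with Cd38 lost it without P1 or P3, and Bst1 with Pax5, Ebf1 with Gfra2 and Csf3r with Pax5 without P1. Itgb7 with Pax5 lost it without P0 (-2.11, adjusted p = 0.0609, limma) or P3 (-2.22, adjusted p = 0.101, limma). Without quality control of cells 20.3% of pairs were positive, against 2.98% with it, and Cd34 with Pax5 (-1.16) and Hoxa9 with Ly86 (-1.05) lost their call, while Cd34 with Gfra2 (-1.92) and with Cd38 (-1.45) stayed called. Cd34 was missing in few cells (16 of the 87 with Gfra2), so its odds ratios rest on small counts. The same holds for Ebf1 with Pax5, with 1 Pax5 cell without Ebf1, at 3.40 with a pseudocount of 1.

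Grouped by the gene lists, the strongest co-detection lay within the B lymphoid list. Its 3 entering genes, Ebf1, Ly6d and Pax5, had a mean log2 odds ratio of 3.92 ± 0.66 (n = 4 plates, limma adjusted p = 5.86e-08), and 3 of their 3 pairs were called, both over all pairs and adjusted over the list alone. Within the stem and multipotent list, Cd34, Hoxa9 and Fli1 had 1.38 ± 0.36 (adjusted p = 2.77e-04), with 1 of 3 pairs called either way. On average over gene pairs, B lymphoid genes were detected apart from the T lymphoid genes Gata3, Cd4 and Cd5 (-0.98 ± 0.35, limma adjusted p = 0.00373). The mean was also negative with the dendritic genes Itgax, Bst2, Csf1r and Id2 (-1.29 ± 0.82, limma adjusted p = 0.00423), with Ly6d, in both lists, left out. With the lymphoid priming gene Ccr7 it was positive (0.80 ± 0.56, limma adjusted p = 0.0285). No B with T lymphoid gene pair was called by itself, nor was Ccr7 with Ebf1 or Pax5. Of the dendritic pairs only Ebf1 with Csf1r, also a myeloid list gene, was called. The value with lymphoid priming lies below the highest list mean, 0.96, of simulated cells that differed in yield alone. Limma drew the spread of each list pair toward that of all 36, which average 1 to 25 gene pairs. The standard error used was smaller than its own SD gives within B lymphoid (0.24), for B with dendritic (0.27) and with lymphoid priming (0.23). It was larger for the stem list and B with T lymphoid. Without P0 the limma adjusted p within B lymphoid fell to 3.2e-21, so these p-values do not measure the spread between plates alone. By limma, the B and dendritic call ended without plate P1 (-1.001, adjusted p = 0.0502), the B and lymphoid priming call without plate P2 (0.58, adjusted p = 0.168) and under 5 other settings, and the stem call with genes in 10% to 90% of cells (0.91). Without quality control of cells the B and T lymphoid value turned to 0.77, B with dendritic lost its call (-0.24), B with lymphoid priming rose to 2.59 and the stem list to 3.44. After seeing the data, 5 more assays were placed in the lists: FOX01, TCF3E2A, CD90.2, CDw199 and CD45RA. CDw199 and CD45RA did not pass the co-detection filter, and only CD90.2 joined the T lymphoid list. B with T lymphoid was then -0.26 (adjusted p = 0.388, limma), B with dendritic was -0.63, and the value within the B lymphoid list fell to 1.91, still called.

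The other lists gave smaller values. Of 36 list pairs, 3 were positive and 2 negative (3 and 4 at an unadjusted p under 0.05). B lymphoid with myeloid genes stood at -0.42 ± 0.25 (adjusted p = 0.235) and with stem and multipotent genes at -0.67 ± 0.97 (adjusted p = 0.235), by limma. The myeloid mean averages called pairs of opposite sign. Csf3r was found apart from Ebf1, Pax5 and Ly6d, and Csf1r apart from Ebf1 (-2.13 ± 0.57) and Ly6d (-1.85 ± 0.56). Klf4 was found with Ly6d (2.35 ± 1.49), Ebf1 (2.04 ± 1.04) and Pax5 (1.90 ± 0.98). These Klf4 pairs lost their call without P0, P1 or P3, and the Csf1r pairs whichever plate was left out. Plate P0 carried the stem and multipotent value, with -2.09 against -0.44, -0.04 and -0.10 on the others, and without it the mean was -0.19 (adjusted p = 0.910). It was called without P2 (-0.88, adjusted p = 0.0313, limma) or P3 (-0.86, adjusted p = 0.00796, limma), both of which keep P0. Within the lymphoid priming list the value was 0.50 ± 0.61, from 1 pair alone, Ccr7 with Ly6d, the latter also a B lymphoid list gene. Within the erythroid and megakaryocyte list the mean was 0.30 ± 0.36, within the T lymphoid list 0.19 ± 0.64, within the dendritic list 0.15 ± 0.19, within the myeloid list -0.08 ± 0.44 and within the NK and innate lymphoid list -0.19 ± 0.44 (SD, n = 4). With 1 plate left out none of these 6 was called, and 3 changed sign, the T lymphoid (-0.03) and NK and innate lymphoid (0.02) values without P2 and the myeloid value (0.09) without P1. No pair was called within the lymphoid priming, erythroid and megakaryocyte, T lymphoid and myeloid lists either way, 2 dendritic pairs were called either way, and 1 NK and innate lymphoid pair over all pairs against 2 adjusted over the list alone.

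**Figure D4:**
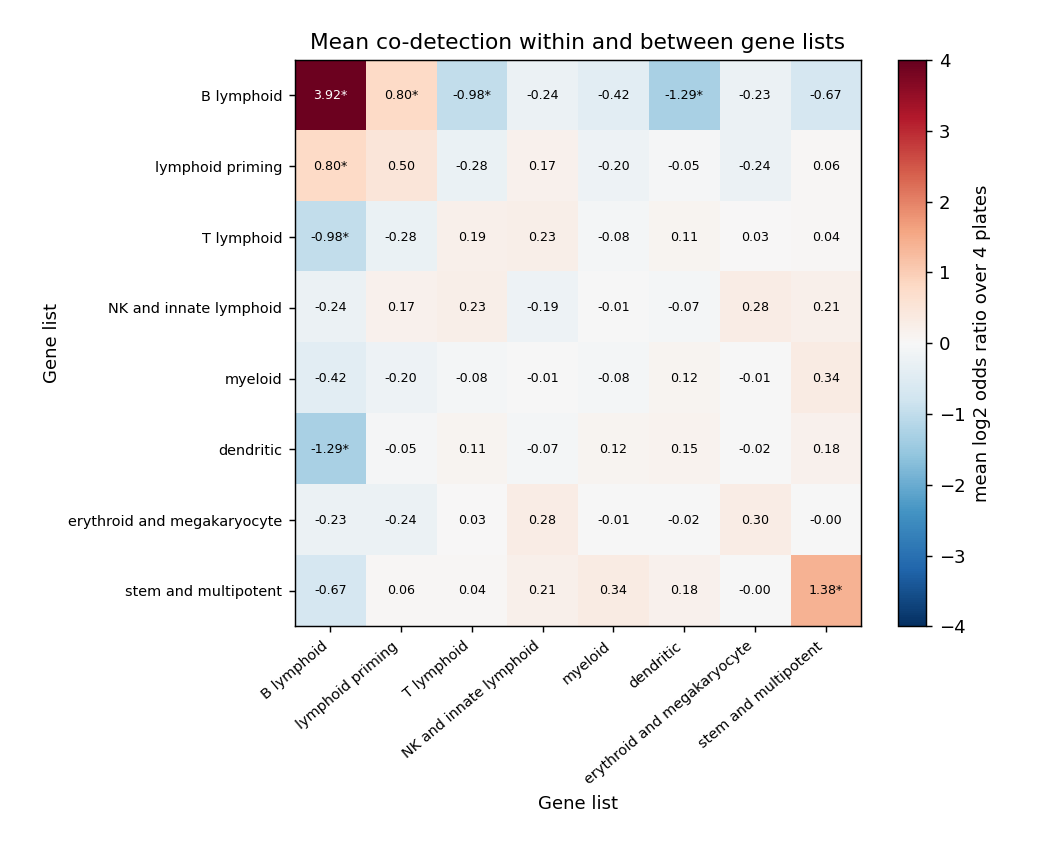
Mean log2 odds ratio of co-detection over 4 plates within (diagonal) and between 8 gene lists; an asterisk marks an adjusted p under 0.05 by limma. The B lymphoid list stands at 3.92 with itself, -0.98 with T lymphoid and -1.29 with dendritic genes.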

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

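Tests chosen only after the result was seen were those of RNA yield for the B lineage genes, of carry-over into no-RT wells, of the cell number in the P0 10-cell well, and the splits of the pooled wells; for genomic DNA and for a constant loss in that well the spread was added to the criterion after the value was seen. Among 72 groups of 4 values looked at for a value far from the others, 5 had one, where chance gives about 1 in 20.

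The 10-cell well of plate P0 stood apart with 29 assays against 68 to 71 in the other 10-cell wells, and with a median level of 2.58 against 15.4 to 18.0. Its median Ct over 29 assays was 25.4. Over these assays the well was a median of 14.7 cycles later than the other 10-cell wells. Fewer cells of usual yield are argued against, since the plate's median single cell came at 14.4. The Ct was 1.38 cycles earlier than that of the plate's latest single cell (-1.38), and 1 of 86 cells was as late. A well with few cells of very low yield therefore stays open. A loss of template or cycles in the whole well cannot be told apart from it: the SD of its shift across assays, 2.76 cycles, passed the bound set beforehand against such a loss, the 2.16 of the widest other 10-cell well, but the 95% interval of their ratio, 0.88 to 1.87, holds 1, and few template molecules widen the shift by sampling alone. No biological explanation was tested.

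Tfrc was detected in 100% of cells on plate P3 and in 98.8% to 98.9% on the others, and Ikzf1 in 98.9% on plate P3 and in 100% on the others. Each of these differences is a single cell per plate. Cd34 and Cd38 had a log2 odds ratio of -3.19 on plate P3 and of -2.13 to -1.94 on the others.

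Ebf1, Ly6d and Pax5 were found in the same cells. Differences in RNA yield as the whole cause are argued against: with cells split by reference gene Ct, the mean log2 odds ratio of the 3 genes was 3.38 (95% interval 2.95 to 3.81). B cells left in the gate, which the B220 gate would remove, are not weighed here and stay open. No biological explanation was tested, since the labels give 1 kind of cell.

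Product in no-RT wells was found for 8 assays in at least 4 of the 16 wells. Carry-over of RNA or cDNA would bring the most abundant transcripts first, but only 2 of the 10 assays with the earliest Ct in cells were among the 8, and H2-K1, Atp5a1 and Ly6d had no product. Genomic DNA of the sorted cell could still be a source and was not decided: across the 8 assays the slope of no-RT Ct on cell Ct was 0.50 (95% interval 0.198 to 0.811). That slope passed the bound set beforehand against genomic DNA by less than its spread, and the bound was ill chosen because cell wells hold the same DNA.

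For detection above no-RT, the splits cannot decide on chance. Of 35 splits of the 8 plate values, 1, the real one, gave 74 assays, and the highest other gave 0. The plate pairs the groups, and only 8 splits part all 4 plates. Among these the highest other also gave 0, but 8 splits are too few for a share under 0.05. A split that mixes cells and no-RT wells also widens the spread within groups, which holds down its calls. The exact limit, which uses no splits, was passed by 46 of the 74 assays and not by 28. For 20-cell against 10-cell wells and for 10-cell wells against single cells, 35 of 35 splits gave at least the real count of 0, so these say nothing against chance (highest other 0). Without the P0 10-cell well, 2 of 35 splits of the 7 wells gave at least the 1 called assay, the highest other giving 1, and chance is not excluded for Zfp521.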

How the results depend on the processing

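Tests added after seeing the data were the exact limit for no-RT wells, leaving out the P0 10-cell well (over the same or all entering assays), the logistic model, a filter on each plate and 5 more assays in the lists; the causes of the changes below were not tested unless named. Of the checks of main results, 22 moved, 10 lost a call and 2 reversed, while all others kept their side of the threshold, a count within 1.5 times or a share within 1 SD. The exact limit left 47 assays above no-RT. With the plate as a block, 73 assays were above no-RT and 0 assays differed in either pooled comparison. In 20-cell against 10-cell wells, 1 assay was called at a Ct limit of 25 and 1 without the P0 10-cell well. Centring on reference genes turned the difference to -0.23, but it takes out a shift shared by all assays, so this reversal does not bear on cell number. Positive pairs were 2.98% and negative pairs 1.62% of those tested; with 1 plate left out, where fewer plates are tested, they ranged from 8 to 27 (0.68% to 2.30%) and from 3 to 16 (0.255% to 1.36%). Without quality control 20.3% of pairs were positive, since empty wells lack all genes; 21 list pairs were then positive and 0 negative (limma; 0.77 for B with T lymphoid, reversed, and -0.24 for B with dendritic). Cells split by number of other genes gave 56 positive and 38 negative pairs (4.76% and 3.23%), split by reference Ct 62 and 38 (5.27% and 3.23%), a pseudocount of 1 67 and 41 (5.697% and 3.49%), and centring 23 positive pairs (1.96%); on simulated independent genes the first of these settings called up to 26 pairs and the pseudocount of 1 up to 28. Of the 54 called pairs, 52 stayed called under both splits and the pseudocount of 1, 42 under centring and 39 under the logistic model, and none changed sign under any setting. Negative list pairs ranged from 1 to 3 with 1 plate left out, B with dendritic from -1.63 to -1.001 and B with lymphoid priming from 0.58 to 1.03. The latter lost its call under stricter quality control (0.79), cells split by number of genes (0.79), centring (0.68), genes in 10% to 90% of cells (0.80) and no-RT assays kept (0.80). The 10% to 90% filter left 1 positive list pair and took the stem list to 0.91, and with 5 more assays 1 negative list pair was called, B with dendritic (-0.63), while B with T lymphoid lost its call (-0.26) and within B lymphoid fell to 1.91. Detection of rare transcripts is limited by the number of cells and by 16 no-RT wells.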

Other observations

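The test of opposed gene sets was chosen after the signs of the called pairs had been seen, though before its own value was. Beyond the B lineage genes, Cd34 was found with Hoxa9 (2.79 ± 1.08), Cd72 (2.77 ± 1.49), Gfi1 (2.35 ± 1.69), Il4ra (2.15 ± 1.15) and Il12rb1 (1.83 ± 0.64), as mean log2 odds ratio ± SD over 4 plates, all called by limma. Cd38, an ectoenzyme of activated and maturing lymphocytes, went with Ly86 (2.00 ± 0.40) and Gfra2 (2.04 ± 0.47) and apart from Hoxa9 (-1.82 ± 0.22) and Il12rb1 (-2.27 ± 0.99). Klrb1c, which encodes the NK1.1 antigen, was found with Pax5 (2.60 ± 1.14), Bst1 (1.92 ± 0.31) and Ly6d (1.78 ± 0.70) and apart from Il2rb, a natural killer cell cytokine receptor chain (-1.75 ± 0.62). Csf1r was found apart from Ebf1 (-2.13 ± 0.57), Ly6d (-1.85 ± 0.56) and Il2rb (-2.06 ± 0.92). Bst2 went with the dendritic gene Itgax (2.22 ± 1.03). These genes were chosen after their values were seen. None of these pairs stayed called without plate P1. Without P3 only Cd34 with Hoxa9 and Klrb1c with Pax5 did, and without P0 only Cd34 with Hoxa9 and Cd72 and Bst2 with Itgax. Cd34 with Gfi1 lost its call whichever plate was left out and was 1.51 without P2. The same loss whichever plate was left out held for Cd34 with Il12rb1, Cd38 with Hoxa9, Klrb1c with Ly6d and with Il2rb, and Csf1r with Ebf1, Ly6d and Il2rb. Bst2 with Itgax also lost its call without P2. Of the 34 called pairs beyond the 20 with the largest values of either sign, 7, 1, 18 and 3 stayed called without P0, P1, P2 and P3.

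The 54 called pairs may reflect a single axis. Of their 26 genes, 22 were linked with each other and parted into 11 with Pax5 (Bst1, Ccr7, Cd38, Ebf1, FOX01, Gfra2, Klf4, Klrb1c, Ly6d and Ly86) and 11 opposite (Cd34, Cd72, Csf1r, Csf3r, Gfi1, Hoxa9, Il12rb1, Il2rb, Il4ra, Itgb7 and TCF), with positive pairs inside a set and negative pairs across. Only 1 called pair, Csf1r with Il2rb, went against the parting, while 200 shuffles of the signs left 6 to 13 pairs against it. Odds ratios of the same cells are not independent of each other, so shuffled signs are a loose comparison, only 11 of the 54 calls stayed without P1, and the axis is a hypothesis.

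Wells 82 and 83 had no product on any of the 4 plates, while wells 23 and 52 were empty on 1 plate each. H2-D1, a class I histocompatibility gene, had a product in 0 of the passing cells (a product in up to 0.865%, if the assay works), in 0 of 16 no-RT wells and in 0 of the pooled wells, while H2-K1 was in 100% of cells. CD284 was detected in 18.6%, 23.0%, 0% and 13.8% of cells on plates P0 to P3, and its pair with Tnfrsf4 (2.79 ± 1.58) rests on the pseudocount on plate P2 and stayed called only without P0. Cd68 was detected in 66.3%, 25.3%, 60.9% and 57.5%.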
